A study of Procambarus clarkii with 12 samples.

How the data were processed

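RNA-seq of the hepatopancreas of male *Procambarus clarkii* was deposited for 12 libraries, 3 each without cadmium and with 2, 5 and 10 mg/L cadmium for 72 h, per the labels. Per the labels' protocols, tissue was flash frozen, total RNA was extracted with Tri Reagent and libraries followed standard Illumina methods. The deposited file of each library gives an estimated count per gene cluster, not normalized, per the file headers and the values. The deposited files also give FPKM, a count scaled by sequence length and library depth, per the file headers. The assembler, aligner, counting tool, reference build and any filter are not given in the sources used here.

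All files listed the same 176325 clusters, of which 10972 had 0 counts in all libraries. Identifiers consist of 2 numbers, and 75.9% of clusters, holding 98.9% of all counts, shared the first number 27942. Of the nonzero estimated counts 58.0% were whole numbers exactly as deposited, as counts of reads divided among similar sequences need not be. Related clusters that share reads are therefore uncertain. The length implied by the deposited counts and FPKM agreed between libraries to a median absolute log2 deviation of 0.007. The files pair no identifier with a gene name, and 0 identifiers matched the RefSeq gene table of assembly FALCON_Pclarkii_2.0. Lists of genes for metal handling, glutathione, antioxidant enzymes, chaperones, digestion, immunity and other cell types, fixed before the data were examined, could not be tested.

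Samples were grouped by their titles, and tests, alternatives and the rule for named identifiers were chosen before the data were examined. The estimated counts were rounded to whole numbers. Clusters were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 57151 clusters with 98.6% of the counts. Counts were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries with edgeR 4.0.16 (glmQLFit, glmQLFTest). Clusters with a Benjamini-Hochberg adjusted p under 0.05 were called. Every call also had a log2 fold change of at least 1 in size. The common biological coefficient of variation was 1.12, the median per cluster 0.905, and the prior degrees of freedom were 1.98. Standard errors of log2 fold changes were derived from the fold change and its F statistic.

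A fold against a group at 0 in all 3 libraries was computed as a lower bound against 3 counts over that group. Such floors cover counting error only. A fit over the 9 treated libraries tested a slope on log2 of the dose. Composition and correlations between libraries were tested exactly over all 15400 partitions into 4 sets of 3. With 3 libraries against 3 an exact test cannot give a p below 0.1. Shared calls were compared with 12 simulations of unchanged groups. In simulated libraries with a dispersion of 0.05, changes at 10 mg/L were set only in clusters with a mean of at least 10 CPM. EdgeR recovered 100% of these 4-fold, 16-fold and 64-fold changes against the controls. In that simulation of 49534 clusters it also called 6 unchanged ones.

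The rule for named identifiers asked for a mean of at least 10 CPM, calls in all 3 comparisons with the controls and the same direction in each, with a log2 fold change of at least 1 in size. It was met by 0 clusters. The 4 identifiers named were instead chosen after their values were seen. They were taken from clusters called over the 4 groups with a mean of at least 10 CPM, 2 that rose and 2 that fell in their larger change from the controls. Those called in most comparisons with the controls came first, then those with the higher mean.

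The alternatives were DESeq2 1.42.0 and its size factors, library size alone, limma 3.58.1 (voom, and on log2(FPKM + 1)), no low-count filter, at least 5 CPM in 3 libraries, a test against a log2 fold change of 1, only the 6 libraries compared, the replicate number as a block and each library left out in turn. With a library left out, the filter was applied anew and kept 65147 to 69389 clusters in comparisons of groups, against 57151. Another pseudocount and filter on FPKM were not run, since counts were tested. A robust fit and a likelihood ratio test were added after the data were seen. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib were used.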

Results

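The data were RNA-seq libraries of the hepatopancreas, the digestive gland of crustaceans, from male red swamp crayfish (*Procambarus clarkii*). Animals were held without cadmium or with 2, 5 or 10 mg/L cadmium, a toxic heavy metal, for 72 h. Each of the 4 groups had 3 libraries, 12 in all. The series title names oxidative stress, histopathology and transcriptome changes under cadmium, and only transcript levels are analysed here. The labels do not say whether a library came from 1 animal or a pool, so p-values measure the spread between these samples. Each library listed the same 176325 gene clusters. The deposited tables give no gene name, so groups of clusters, libraries and 4 identifiers, chosen after their values were seen, are described.

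Total estimated counts per library were 21160462, 20548772 and 19490723 in the controls and 15835744, 16905766 and 17480371 at 2 mg/L. They were 20848163, 21653867 and 19011151 at 5 mg/L and 16083833, 16339501 and 16880989 at 10 mg/L. The totals differed among the 4 groups (exact permutation test over all 15400 partitions, p = 0.00571). The 2 and 10 mg/L libraries lay below every control and 5 mg/L library, so a difference of depth cannot be separated from those groups. Comparisons of 5 mg/L with the controls and of 10 with 2 mg/L were between libraries of like depth. Clusters detected with at least 1 count numbered 100804 ± 5326 in the controls, 93751 ± 5137 at 2 mg/L, 104050 ± 2224 at 5 mg/L and 94717 ± 9193 at 10 mg/L (mean ± SD, n = 3 each). No difference among groups was detected by the same exact test (p = 0.179), nor after thinning to one total (96866 ± 5049, 92871 ± 5899, 100025 ± 1165 and 94212 ± 9493 in the same order, SD, n = 3 each, exact permutation p = 0.529). None was detected for the share of counts in the 1000 most abundant clusters (exact permutation p = 0.675). The cluster with the most counts over all 12 libraries held 3.75% ± 2.02 of counts in the controls and 1.72% ± 0.817 at 10 mg/L (SD, n = 3), with exact permutation p = 0.275 over the 4 groups.

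Libraries of a group resembled each other more, on average, than libraries of different groups. Over the 57151 tested clusters the mean Spearman correlation of log2 CPM was 0.597 within groups and 0.557 between them. Of all 15400 partitions of the libraries into 4 sets of 3, the difference was at least as large in 3, the labelled grouping included (exact permutation p = 0.000195, one-sided). The 2 mg/L libraries correlated most closely with each other (mean 0.630), followed by the controls (0.611), the 5 mg/L libraries (0.582) and the 10 mg/L libraries (0.566). Pairs of a control and a 10 mg/L library had a mean of 0.535, and pairs of a control and a 5 mg/L library 0.583, about that of the 5 mg/L pairs. On the first principal component the 10 mg/L replicates 1 and 2 scored 297 and 295, while 10 mg/L replicate 3 scored 0.58, among the other groups. That library had a mean correlation of 0.537 with its own group, 0.576 with the controls and 0.574 with the 5 mg/L libraries. It also had the fewest clusters detected, 84435. The 2 mg/L libraries were set apart on the second component. On the third component 10 mg/L replicate 3 scored 292, and the next highest library, 2 mg/L replicate 3, scored 123.

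**Figure D1:**
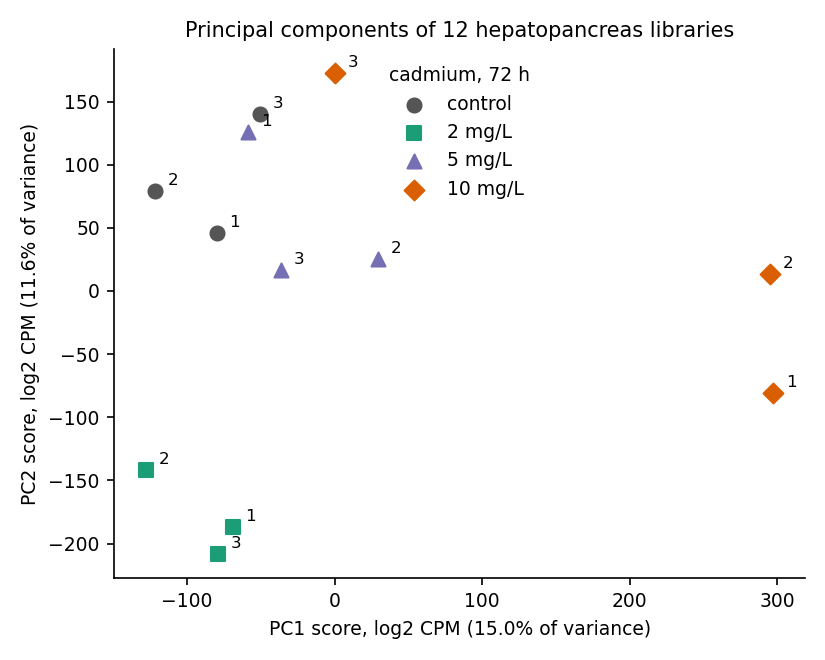
Scores of the 12 libraries on the first and second principal components of log2 CPM, marked by cadmium group and numbered by replicate. At 10 mg/L, replicates 1 and 2 lie at 297 and 295 on the first component and replicate 3 at 0.58.

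Levels of single clusters varied widely between libraries of a group. The median within-group coefficient of variation was 63.8% for the 24680 tested clusters at 1 to 10 CPM. It was 43.7%, 42.7% and 45.8% for the 6219, 1034 and 141 clusters in the next classes, 10 to 100, 100 to 1000 and over 1000 CPM. A library with 0 counts occurred in 46.2% of clusters at 1 to 10 CPM and still in 21.6% at 10 to 100 CPM. In simulated 10 mg/L and control libraries with this spread, changes were set only in clusters with a mean of at least 10 CPM, 33 or 34 per fold and direction. Recovery in clusters of lower mean was not simulated. EdgeR recovered 0% of the 4-fold changes. It recovered 30.3% of rises and 9.09% of falls of 16-fold, and 51.5% and 42.4% at 64-fold. In the same simulation of 48931 clusters, 1 of the unchanged ones was also called.

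At 2 mg/L against the controls, 1 cluster was higher and 4 were lower. Cluster-27942.52731 had 0 counts in all 3 controls and 14.1 ± 3.37 CPM at 2 mg/L (SD, n = 3), at least 275-fold higher against a floor of 3 counts over the control group (edgeR quasi-likelihood test, adjusted p = 0.0150). Cluster-27942.49753 fell from 44.9 ± 13.6 CPM to 1.30 ± 0.21 CPM (SD, n = 3), a log2 fold change of -5.10 with standard error 0.44 (edgeR adjusted p = 0.0137). In 4 of the 5 called clusters 1 of the 2 groups had no counts. Groups of 3 libraries did not overlap in 15.3% of tested clusters, where chance gives 10%. Unadjusted p was under 0.05 for 3716 clusters, against 2857.55 expected with no differences. DESeq2 called 1295 clusters and limma-voom 5 (3 higher, 2 lower), of which 1 was also called by edgeR. Without control replicate 1 or 2 or 2 mg/L replicate 3 edgeR called 0 clusters, without control replicate 3 it called 3, and without 2 mg/L replicates 1 and 2 in turn 13 and 16. Leaving out 1 library of the other doses gave 2 to 6 calls.

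At 5 mg/L against the controls no cluster passed the edgeR test, and the smallest adjusted p was 0.0510. Unadjusted p was under 0.05 for 3149 clusters. Groups did not overlap in 12.3% of clusters, where chance gives 10%. Cluster-27942.63967 had 57.2 ± 17.0 CPM at 5 mg/L and 3.38 ± 0.53 CPM in the controls (SD, n = 3), a log2 fold change of 4.08 with standard error 0.45 (edgeR adjusted p = 0.0559). Cluster-27942.52731 had 5.25 ± 2.49 CPM at 5 mg/L, at least 102-fold higher than the control floor (edgeR adjusted p = 0.0551). DESeq2 called 1005 clusters (519 higher, 486 lower), limma-voom 4 and limma on log2(FPKM + 1) 105. Without 5 mg/L replicate 2 or 3 or 10 mg/L replicate 1, edgeR called 1 cluster. Without 2 mg/L replicate 1, outside the comparison but part of the fit, it called 7, of which 5 were higher and 2 lower.

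At 10 mg/L against the controls, 1 cluster was higher and 3 were lower, each with no counts in 1 of the 2 groups. Cluster-27942.52731 was the one that rose, to 28.0 ± 13.6 CPM (SD, n = 3), at least 546-fold above the control floor (edgeR adjusted p = 0.0265). Cluster-27942.63033 fell from 11.6 ± 5.60 CPM (SD, n = 3) to 0 counts in all 3 libraries at 10 mg/L, at least 191-fold lower (edgeR adjusted p = 0.0265). Unadjusted p was under 0.05 for 6487 clusters, 11.4% of those tested. Groups did not overlap in 16.8% of clusters, where chance gives 10%. The size of the called set rested on 10 mg/L replicate 3: without it 247 clusters were called, 167 higher and 80 lower. Without any 1 of the other 11 libraries 0 were called. Each of those fits also tested more clusters, 65147 to 69389, so the loss cannot be laid to the left-out library alone. DESeq2 called 3241 clusters on all libraries (1641 higher, 1600 lower), and limma-voom 0.

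**Figure D2:**
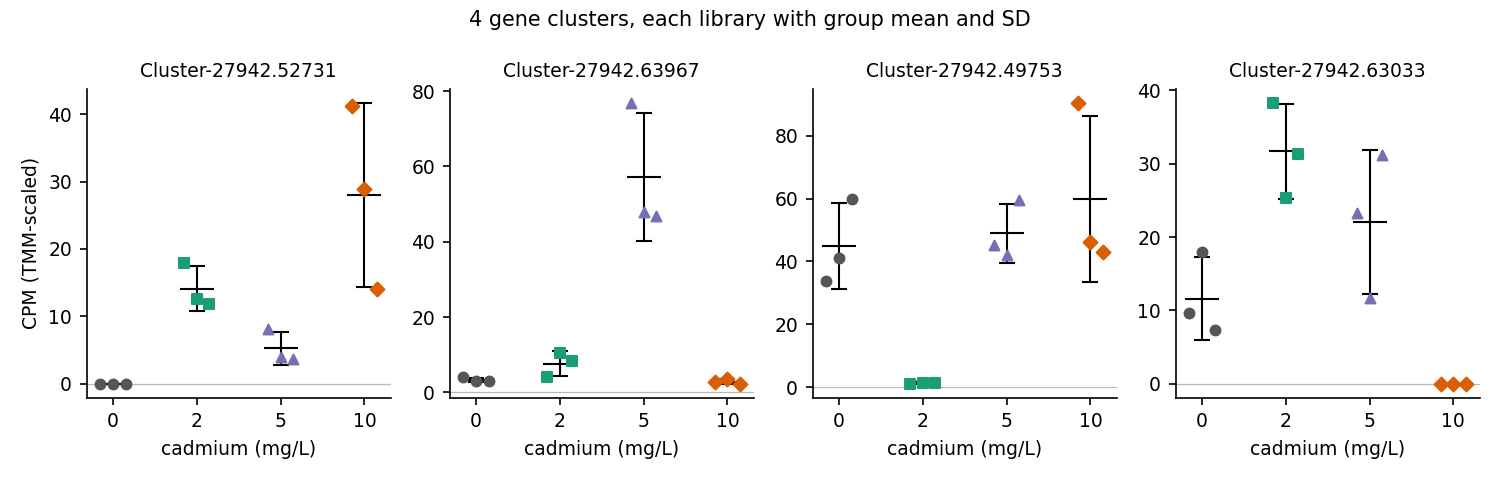
CPM of 4 gene clusters in each library (points) against cadmium in mg/L, with the group mean and SD (bars, n = 3). Cluster-27942.52731 has 0 counts in the 3 controls, Cluster-27942.63967 reaches 57.2 CPM at 5 mg/L, Cluster-27942.49753 lies at 1.30 CPM at 2 mg/L, and Cluster-27942.63033 has 0 counts at 10 mg/L.

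The doses were also set against each other in the same fit. From 2 to 5 mg/L, 4 clusters were higher and 2 lower, Cluster-27942.49753 among the former (48.9 ± 9.33 CPM at 5 mg/L, SD, n = 3, edgeR adjusted p = 0.0109). From 5 to 10 mg/L, 2 were higher and 4 lower. Cluster-27942.63967 fell to 2.89 ± 0.60 CPM (SD, n = 3), a log2 fold change of -4.30 with standard error 0.45 (edgeR adjusted p = 0.0303). From 2 to 10 mg/L, 4 were higher and 3 lower. Cluster-27942.63033, at 31.7 ± 6.45 CPM at 2 mg/L (SD, n = 3), was at least 521-fold lower at 10 mg/L (edgeR adjusted p = 0.00998). Of the 6, 6 and 7 clusters called in these comparisons, 5, 5 and 6 had no counts in 1 of the 2 groups. DESeq2 called 1150, 1870 and 2929 clusters in the same comparisons. Without 10 mg/L replicate 3 edgeR called 199 clusters between 5 and 10 mg/L and 159 between 2 and 10 mg/L. Between 2 and 5 mg/L, leaving out 2 mg/L replicates 1, 2 and 3 gave 0, 14 and 0 calls, and 5 mg/L replicates 1 and 3 gave 1 and 10. Between 5 and 10 mg/L, leaving out 5 mg/L replicates 1 and 2 gave 0 and 3 calls and 10 mg/L replicate 1 gave 1. Between 2 and 10 mg/L, leaving out 2 mg/L replicates 1 and 2 gave 12 and 16 calls, and 10 mg/L replicates 1 and 2 gave 12 and 14. Leaving out a library of neither group gave 0 to 7, 0 to 10 and 5 to 10 calls in these 3 comparisons.

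Over the 4 groups together 10 clusters differed (edgeR quasi-likelihood F test, smallest adjusted p = 0.0455), and 4657 had an unadjusted p under 0.05. The 4 identifiers named here were chosen from these 10. Without 10 mg/L replicate 3, 177 clusters were called. Without 2 mg/L replicate 1, 5 mg/L replicate 2 or 10 mg/L replicate 1 the numbers were 7, 2 and 1, and without any 1 of the other 8 libraries 0. For a slope on log2 dose among the 9 treated libraries edgeR called 0 clusters (smallest adjusted p = 0.333). Unadjusted p was under 0.05 for 3762 of 48862 clusters, where 2443.1 are expected with no differences and 49 other orders of the libraries gave 688 to 3107.

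**Figure D3:**
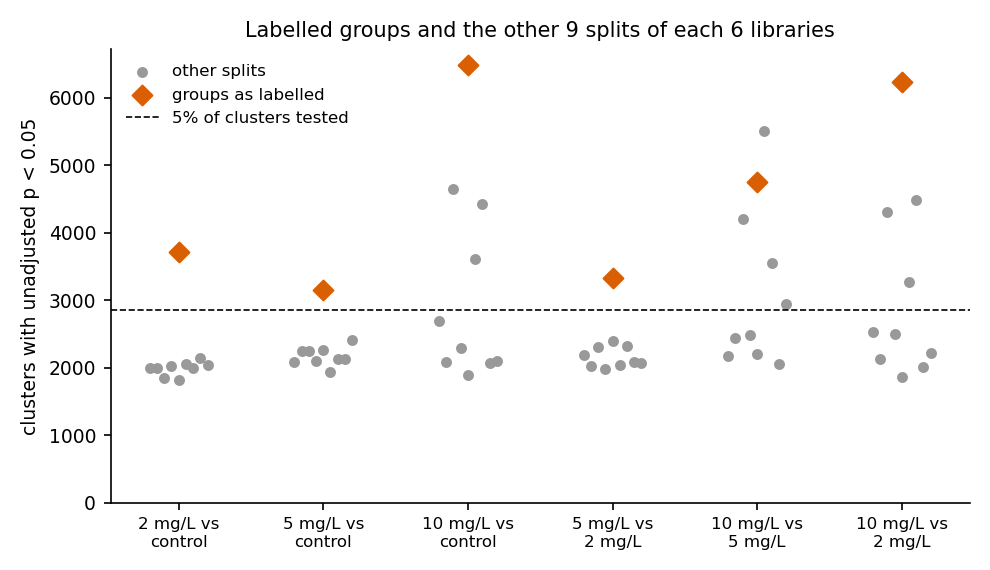
Number of clusters with unadjusted p under 0.05 (vertical axis) in each comparison (horizontal axis) for the groups as labelled (diamonds) and the other 9 splits of the same 6 libraries (grey points), with 5% of the tested clusters as a dashed line. The labelled groups give the most in 5 of the 6 comparisons, and between 5 and 10 mg/L they give 4751 against 5514 for 1 other split.

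The question of shared changes between doses rested on few calls. Cluster-27942.52731 was called at both 2 and 10 mg/L and no cluster at all 3 doses. Simulated unchanged groups shared 0 calls, but independent lists of their calls would share 0 as well. For the observed calls, independent lists would share 1.75e-05 rising clusters, a value that ignores the controls common to both comparisons. Neither value tests the shared call. With an unadjusted p under 0.05, 759 clusters were higher and 460 lower at both 2 and 10 mg/L. Simulated unchanged groups shared 490 and 177. Independent lists of the observed sizes would share 83.5 and 128, and those of the simulated sizes 29.0 to 33.0 and 29.5 to 34.4. The simulated lists were thus smaller, so the higher observed numbers do not show more sharing than in unchanged groups. Log2 fold changes against the controls at 2 and 10 mg/L correlated across clusters with r = 0.42, below the 0.499 of the simulated groups. Their covariance was 0.859, above the simulated 0.731. For 2 and 5 mg/L the covariance was 0.827 against 0.735, and for 5 and 10 mg/L 0.939 against 0.732. The spread between the 3 controls alone would give a covariance of 0.719. For 2 and 10, 2 and 5, and 5 and 10 mg/L the covariances exceeded it by 0.140, 0.108 and 0.220. That spread therefore does not give the whole covariance. A difference common to all 3 controls may still contribute, since 3 libraries cannot be split and the simulated controls were also drawn from a common mean.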

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

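The robust fit, the likelihood ratio test, the thinned and abundant-cluster settings of agreement, and the left-out settings of agreement and composition were chosen after the data were seen. Counts of calls are given for 2, 5 and 10 mg/L against the controls, then 5 against 2, 10 against 5 and 10 against 2 mg/L, and the cause of each shift was not tested unless stated. The numbers were 5, 0, 4, 6, 6 and 7 as reported. DESeq2 called 1295, 1005, 3241, 1150, 1870 and 2929 clusters, and these included every cluster edgeR called. The edgeR likelihood ratio test, which ignores the uncertainty of the dispersion, called 537, 362, 1339, 535, 840 and 1161. Limma on log2(FPKM + 1) called 65, 105, 74, 68, 85 and 72. Limma-voom called 4 at 5 mg/L, 0 at 10 mg/L, 10 for 5 against 2 and 3 for 10 against 2 mg/L. DESeq2 size factors gave 2 calls at 5 mg/L, and the robust fit and the filter of 5 CPM gave 4 each. No low-count filter gave 3 for 5 against 2 mg/L, and library size alone gave 3 for 10 against 5 mg/L. Fits to only the 6 libraries compared called 0 in all 6 comparisons, with fewer residual degrees of freedom. Apart from the replicate block and the left-out libraries, given below, settings not listed stayed within 1.5 times the reported number.

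With each of the 12 libraries left out in turn, the ranges of calls were 0 to 16, 0 to 7, 0 to 247, 0 to 14, 0 to 199 and 5 to 159, and 0 to 177 over the 4 groups. The values 247, 199, 159 and 177 came from leaving out 10 mg/L replicate 3. Over the 4 groups, no low-count filter gave 0 calls, with 11845 clusters at an unadjusted p under 0.05 by edgeR. A dose slope over all 12 libraries in mg/L gave 2 calls, both rising, while every other dose setting gave 0. The overlap of calls was 1 cluster in each of the 3 settings run for it, and it is lost wherever 0 clusters are called at 10 mg/L, as by limma-voom. The within-group minus between-group correlation stayed between 0.0340 and 0.0545 with each library left out. It was 0.0401 after thinning to 15835655 counts and 0.0656 in clusters of at least 10 CPM, with exact p of at most 0.00318 in all these settings.

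With the replicate number as a block, calls were 0 in all 6 comparisons, over the 4 groups and for the dose slope. The numbers did not pair the samples: the 18 correlations of deviations between same-numbered libraries ran from -0.067 to 0.050, 0 exceeded 0.1, and 4 of 12 libraries correlated best with their own number. Each named cluster was followed in 1 comparison only. With each of the 12 libraries left out, adjusted p by edgeR ran from 0.00906 to 0.0728 for Cluster-27942.49753 at 2 mg/L against the controls. At 10 mg/L against the controls it ran from 0.0127 to 0.113 for Cluster-27942.52731 and to 0.118 for Cluster-27942.63033. For Cluster-27942.63967 between 5 and 10 mg/L it ran from 0.0250 to 0.171. That call was also lost with no low-count filter (0.122), library size alone (0.0509) and the test against a log2 fold change of 1 (0.0512). Limma-voom lost Cluster-27942.52731 (0.115) and Cluster-27942.63033 (0.150), and limma on log2(FPKM + 1) gave the latter a log2 fold change of -1.33 (0.212). The block and the fits to 6 libraries lost all 4, with adjusted p of at least 0.131. Under the block the fold changes of the 2 named clusters with counts in every group hardly moved. The log2 fold change was -5.09 for Cluster-27942.49753 and -4.32 for Cluster-27942.63967, against -5.10 and -4.30 as reported. For Cluster-27942.52731 and Cluster-27942.63033, each with a group at 0, it depended on the method. Limma-voom gave 9.97 and -8.46, and limma on log2(FPKM + 1) gave 3.31 and -1.33. After thinning, clusters detected at 2 and 10 mg/L minus the controls went from -7052 to -3995 and from -6087 to -2654. With libraries left out, the difference ran from -9283 (without 2 mg/L replicate 1) to -3992 (control replicate 1) at 2 mg/L. At 5 mg/L it was 3247 and ran from 1454 (control replicate 2) to 6307 (control replicate 1), and at 10 mg/L from -9801 (10 mg/L replicate 2) to -946 (10 mg/L replicate 3). At 10 counts or more the 10 mg/L difference was -2413 before and 1925 after thinning. The median within-group coefficient of variation was still 45.8% above 1000 CPM, where counting error is small, so depth was not the main limit on the calls for abundant clusters.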

Other observations

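The tests of regrouped libraries, of neighbouring identifiers, of simulated calls, of correlation with other groups, of exchanged labels and of the left-out library were chosen after the results were seen. Some clusters were absent from 1 group. Clusters at 0 in all 3 libraries of a group and at 10 counts or more in the other 9 numbered 2 for the controls, 13 at 2 mg/L, 6 at 5 mg/L and 15 at 10 mg/L. The 216 sets of 3 libraries from mixed groups had a mean of 4.50 such clusters and at most 14. The 2 of the controls lay below that mean, and the 13 at 2 mg/L below that maximum. The total of 36 over the labelled groups was reached by 58 of all 15400 partitions, the labelled one included, with 42 in the highest other. For this total, chance can be excluded at the 0.05 level. That does not separate dose from other differences between the groups, such as the lower depth at 2 and 10 mg/L. Clusters with 10 counts or more in 1 group and 0 elsewhere numbered 10, 14, 12 and 13 in the same order. Mixed sets had a mean of 5.97 of these and at most 26, more than any labelled group. Their total of 49 was reached by 41 of the 15400 partitions, with 58 in the highest other.

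Regrouping the libraries gave counts of calls to set beside those of edgeR. With 3 against 3 there are 10 splits, too few for a share under 0.05. At 2 mg/L against the controls the labelled groups gave 5 calls and the highest other split 1, and 1 of the splits gave as many, the labelled one. At 5 mg/L the values were 0 and 2, and a count of 0 is reached by all 10 splits whatever the data, so it decides nothing. There the clusters at p under 0.05 were 3149 as labelled and at most 2411 in another split. At 10 mg/L the calls were 4 and 4, from 2 splits. For 5 against 2, 10 against 5 and 10 against 2 mg/L they were 6 and 8, 6 and 7, and 7 and 7, with 2 splits each. Over the 4 groups the labelled grouping gave 10 calls and the highest other grouping drawn gave 2, so 1 of 50 gave as many and chance can be excluded at the 0.05 level. The dose slope had 0 calls, which all 50 drawn orders reach by design, with 1 in the highest other, so that count decides nothing either. Its clusters at p under 0.05 numbered 3762, the most of the 50 orders (highest other 3107), which does not separate a slope from other differences between the doses. The within-group minus between-group correlation of 0.0403 was reached by 3 of 15400 partitions, the highest other being 0.0438, and chance can be excluded. Excluding chance does not separate cadmium from any other difference between the groups.

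Of the 12142 clusters with a mean of at least 5 CPM, 3049 (25.1%) had 0 counts in at least 1 library, and sampling at this depth is argued against, since 0 such clusters are expected from counting error alone. A candidate explanation is that reads were divided between related clusters. Among pairs with neighbouring identifier numbers and such a member, 3.10% had a correlation under -0.8, against 0.228% of random partners, a ratio of 13.6 (38 of 1226 and 56 of 24517 pairs, Fisher's exact p = 7.3e-26). Random partners were drawn 20 times for each member, and Fisher's test takes pairs as independent. Its p therefore overstates the evidence. Among neighbours, correlations above 0.8 were also more frequent, 4.32% (53 pairs) against 0.494%, which divided reads do not predict. In those of these pairs with a correlation under -0.8 the sum varied less relative to its members in neighbours than in random partners. The difference was 0.288 (0.348 against 0.636). Divided reads may cover only a small part of the 3049 clusters, and differences between animals stay open as untested. Most clusters that edgeR called between groups had a group at 0 counts. Whether divided reads contributed to those calls or their folds was not tested.

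The library of 10 mg/L replicate 3 stood apart from the other 2 of its group, and lower sequencing depth is argued against, since 83547 clusters were detected after thinning to one total, still the fewest, while its own total was not the lowest. A control library under a wrong label cannot be told apart. The highest correlation of 10 mg/L replicate 3 with a control was 0.582, below the lowest between 2 controls, 0.602. By the mark first written for this correlation, that counts against a control library. The gap of 0.0202 is no wider than the range of the control pairs, 0.0206, so it is not taken as decisive. This library shared 28 absent or group-specific clusters with the other 10 mg/L libraries, where controls shared at most 18. That is short of the 2-fold excess set beforehand. With the 3 pairs of controls it shared 14, 10 and 6 such clusters, where the controls shared 12. A 5 mg/L library under a wrong label cannot be told apart either, with a highest correlation of 0.596 (5 mg/L pairs began at 0.568) and 27 clusters shared by 5 mg/L replicate 2. With the 3 pairs of 5 mg/L libraries 10 mg/L replicate 3 shared 17, 10 and 9 such clusters, where the 5 mg/L libraries shared 18. On the third principal component it scored 292, where controls scored -119 to -65.4 and 5 mg/L libraries -134 to -15.0. That component sets it apart from both groups, but no mark was set for it beforehand and it rests on 1 library. Labels exchanged with 5 mg/L replicate 2 cannot be told apart as well. Of 54 exchanges of 2 libraries this 1 raised the correlation difference, to 0.0438. It also raised clusters at p under 0.05 between 5 and 10 mg/L from 4751 to 5514, but group-specific clusters went from 85 to 83. Going against an exchange, 5 mg/L replicate 2 correlated at 0.539 with each of 10 mg/L replicates 1 and 2, which correlated at 0.625. It correlated more closely with the other 5 mg/L libraries, at 0.568 and 0.572. On the first component it scored 29.7, far from the 297 and 295 of those 10 mg/L libraries. Variation between samples at the highest dose may equally stand behind the position of 10 mg/L replicate 3 and was not tested. Its composition differed too, with 77.1% of counts in its 1000 most abundant clusters, the most of all 12 libraries. Replicates 1 and 2 of its group had 66.1% and 66.6%. Its TMM factor was 0.807, against 1.15 and 1.11 in those 2. Whether this composition stands behind its position was not tested.

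DESeq2 called 3241 clusters at 10 mg/L against the controls where edgeR called 4. Calls on variable clusters that did not differ may contribute: with the spread of these libraries DESeq2 called 420 unchanged simulated clusters and edgeR 1, a ratio of 420 that rests on that single call. The 420 is well below 3241. Splits that mix the 10 mg/L and control libraries gave 550 to 1751 DESeq2 calls, all above 420. The simulation therefore sets no bound on the share of such calls. In the 10 splits of the libraries DESeq2 gave 3241 calls for the labelled groups and 1751 in the highest other at 10 mg/L, 1295 and 651 at 2 mg/L, and 1005 and 696 at 5 mg/L, with 1 split as high in each and too few splits for a share under 0.05. Real differences that edgeR did not call stay open, as edgeR recovered fewer of the simulated changes.

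The 247 clusters called without 10 mg/L replicate 3 were looked up in that library, which had no part in the call. Of the 167 higher at 10 mg/L, 41.9% lay above all 3 controls in it, against 50.3% to 76.6% in the 2 and 5 mg/L libraries. Of the 80 lower, 65% lay below all 3 controls in it, against 31.2% to 43.8% in those libraries. Over all 247 the share was 49.4%, within the 46.6% to 66.0% of those libraries. That library had the fewest clusters detected, 83547 after thinning, a cluster at 0 counts in it lies at or below the controls, and 56 of the 247 were at 0 in both other 10 mg/L libraries, so the 65% alone does not show a shared response. Chance gives 25% for a library like the controls, before the choice of clusters on the same controls is counted.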
